A study of Rattus norvegicus with 10 samples.

How the data were processed

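White adipose tissue of 10 male rats, 13 weeks old, was profiled on 1 rat expression array per animal. Per the labels' protocols, total RNA was cleaned on a column and 100 ng of it was turned into biotin-labelled cRNA. The extraction text in the labels speaks of a brain sample, while the tissue field, the sample names and the series title give white adipose tissue. The levels of adipocyte and brain marker lists were therefore measured and are given with the results. The labels give 30 days of feeding in one place and 4 weeks in another.

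The deposited table holds 1 value per probe set and array, taken here as log2 from its range. The base of the logarithm, the background correction, the summarisation and the normalization that the authors used are not given in the sources used here. The table has 31099 probe sets, of which 57 are control probe sets of the array and were left out of the tests. Of the 31042 probe sets tested, 20826 have 1 gene symbol in the platform annotation, 436 have several and 9780 have none. Of the single-gene probe sets, 20758 were matched to the current gene table by their gene identifier, and 0 symbols changed. These probe sets represent 14217 genes. Where a gene had several, the probe set with the highest mean over all 10 arrays stood for it, and it stayed the same under each alternative except those that change the choice of probe set or leave it out.

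The values are unusually flat. The SD over the 10 arrays was under 0.001 for 90.9% of the probe sets and above 0.01 for 8.4% of them. The 2607 probe sets above 0.01 are called variable below, and the other 28435 are called compressed. This division was made after the data were examined and without regard to the groups. Why most values are this flat is not known from the sources used here, so a fold is a fold on the deposited scale, and the size of a difference cannot be set against that of another probe set. The precision is limited by the 5 arrays per group.

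The groups were taken from the diet field of the labels. Each animal is 1 sample, the groups share no animal numbers and the labels do not say which animals were fed as pairs, so no pairing was used. The comparison was always noodle with seasoning minus control without seasoning. It was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Gene lists were tested with camera from limma at a preset correlation of 0.01, for lists with at least 5 measured genes, with adjustment over the lists. Camera sets a list against the other genes, so higher and lower in its calls mean relative to them. Camera with an estimated correlation and fry, which tests whether a list moves one way or, in its mixed form, either way, stood beside it. The 55 lists cover lipid metabolism, other pathways, RNA quality and cell types, and 919 of their 1062 gene entries were measured. For each list the number of genes past the threshold was also counted after adjustment over the list alone. Differences of single measures between the groups were tested with two-sided exact permutation tests over all 252 assignments of the arrays, whose smallest possible p is 0.0079.

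The design, the lists, the main alternatives and the rule for the named genes were fixed before the data were examined. The rule took the 6 genes with the smallest p in each direction where none passed the threshold, up to 4 genes with the smallest p from each list that passed and from each list of lipid metabolism, and 12 genes of fat tissue named in advance. Of the genes taken from lists, values are given for those with a variable probe set, a restriction set after the data were examined. The rule was widened after the data were examined by the 12 variable genes with the smallest p in each direction, the members of the clock list, and Cish and Bcl6.

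The alternatives were quantile normalization, centring of each array on its median, filters on dim probe sets, a floor at the 20th percentile, another variance prior, array weights, the animal number or the 3-prime to 5-prime difference of the Actb and Gapdh control probe sets as a covariate, the mean of a gene's probe sets, another representative probe set, leaving out each animal in turn, and a rank product over the 25 pairs of arrays with 50 permutations. A test on variable probe sets only and the hybridization controls as a covariate were added after the data were examined.

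The tests were tested on simulated data with the means and within-group spreads of the real probe sets. Of 200 variable probe sets changed among the 31042, limma found 34.8% of those changed by 0.5 log2 units, 79% of those changed by 1 and 96.5% of those changed by 2, and 5.47% of its calls were false. In 20 simulations of 14217 genes with no change and independent noise, camera called 0 lists per simulation, and with 1 list shifted by 1 SD it called that list in 100% of them. In the real data, the lists that passed had estimated correlations from 0.13 for the proteasome to 0.656 for mesothelial markers. Simulations with independent noise therefore do not show how often camera calls unchanged lists in these data. In the clock list, 74.7% of genes shifted by 2 SD passed after adjustment over the list alone. This share also comes from independent noise, so it may differ for genes that vary together. In 5 simulations with no change and 10 permutations each, the rank product called 754 to 842 of the 31042 probe sets when each kept its own spread, and 0 to 2 when all had 1 spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.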

Results

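Gene expression in white adipose tissue was measured in 10 male rats. The noodle group of 5 rats ate a diet with 30% by weight of instant noodle with its seasonings, in which fat gave 26% of the energy. The control group of 5 rats is described as fed the same diet without the seasonings. Whether that diet held the noodle, and its fat content, are not given in the sources used here. Both groups were pair-fed at about 60 g of diet per kg of body weight per day for 30 days. The series' named subject is lipid metabolism under the seasonings, and the comparison is of the noodle diet with the control diet, which bears on the seasonings alone only if the diets were otherwise alike. Array medians lay between 6.17 and 6.18 on the log2 scale, and correlations between arrays lay between 0.993 and 0.998. The 19 measured adipocyte markers had a median level of 11.5, with Car3, a carbonic anhydrase abundant in fat, the highest at 13.6. The 19 brain markers had a median level of 5.75, below the array median, with the myelin gene Mbp the highest at 8.76.

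No probe set passed the threshold between the diets. Of 31042 probe sets tested with limma, 0 reached an adjusted p of 0.05, and the lowest adjusted p was 0.409. At an unadjusted p under 0.05 there were 1481 probe sets, 770 higher and 711 lower in the noodle group, where chance alone gives 1552.1. Among the 2607 variable probe sets, 212 reached an unadjusted p under 0.05, 73 higher and 139 lower, where chance gives 130.35. The groups did not overlap at all in 25 variable probe sets, or 0.959% of them, where chance gives 0.794%. Leaving out control animal 14 brought 1 probe set past the threshold, that of Emg1. The rank product called 961 probe sets, 400 higher and 561 lower, but it also called 754 to 842 in simulated data with no change.

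**Figure D1:**
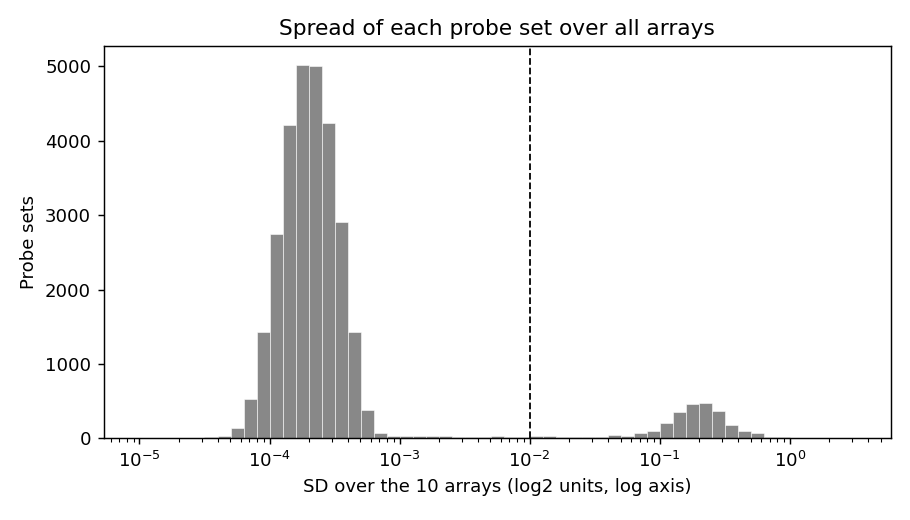
Number of probe sets by their SD over the 10 arrays, in log2 units on a log axis. The dashed line marks an SD of 0.01, which 8.4% of the probe sets exceeded.

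The clock genes, which keep daily time in most tissues, held the most genes that passed after adjustment over the list alone. Of 17 measured members, 8 passed when adjusted over the list alone and 0 when adjusted over all genes tested. This list was singled out after the values were seen, and across all 55 lists 11 entries in 4 lists passed in this way. As a whole, the clock list did not pass on the deposited values. Its adjusted p was 0.42 in camera and 0.634 in the mixed form of fry. Higher in the noodle group were Bmal1 and Npas2, which encode activators of the clock, by 0.74 ± 0.20 (SE, n = 5 per group) and 0.67 ± 0.15 log2 units. Cry1 and Nfil3 were higher by 0.34 ± 0.09 and 0.52 ± 0.19. Lower were Dbp, a clock-driven transcription factor, with a difference of -1.17 ± 0.43 or 2.26-fold, and the period genes Per3 and Per2, with differences of -0.58 ± 0.19 and -0.46 ± 0.17. The eighth gene, Clock, has a compressed probe set. Bmal1 and Cry1 were above every control animal in 5 of 5 noodle rats, and Dbp was below every control animal in 3 of 5. In noodle animals 10 and 13 Bmal1 stood at 6.32 and 6.36, near the highest control at 6.21. In noodle animals 1, 4 and 7 it stood at 7.06 to 7.22. Dbp in noodle animals 10 and 13, at 8.32 and 8.29, lay within the control range of 8.01 to 8.85.

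Other clock genes pointed the same way without passing. Nr1d1 and Nr1d2, which repress Bmal1, had differences of -0.66 ± 0.30 and -0.45 ± 0.18. Bhlhe41 differed by -0.67 ± 0.30, Tef by -0.46 ± 0.20 and Per1 by -0.30 ± 0.20 (-0.408 to -0.18 without single animals). Within the list the adjusted p reached 0.0497 for Dbp, Per2 and Nfil3, close to the threshold, and 0.0603 for Nr1d2. The SD of Dbp was 0.917 in the noodle group and 0.357 in the controls, and that of Per2 was 0.268 and 0.271. The count of 8 fell to 0 when noodle animal 1, 4 or 7 or control animal 2, 5, 8 or 14 was left out, and was 13 without noodle animal 10, 10 without noodle animal 13 and 6 without control animal 11. It also fell to 0 with the 3-prime to 5-prime difference of the Actb and Gapdh control probe sets as a covariate. There Bmal1 differed by 0.73 ± 0.27 and Dbp by -1.13 ± 0.58, near their sizes without it but with larger errors. Npas2 shrank to 0.515 ± 0.19 and Per3 to -0.48 ± 0.25, while Per2 grew to -0.58 ± 0.22 and Nr1d1 to -0.80 ± 0.41. The 3-prime to 5-prime difference, a sign of RNA quality, was 0.84 ± 0.07 in the noodle group and 0.95 ± 0.08 in the controls (SD, n = 5, exact permutation p = 0.0476).

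**Figure D2:**
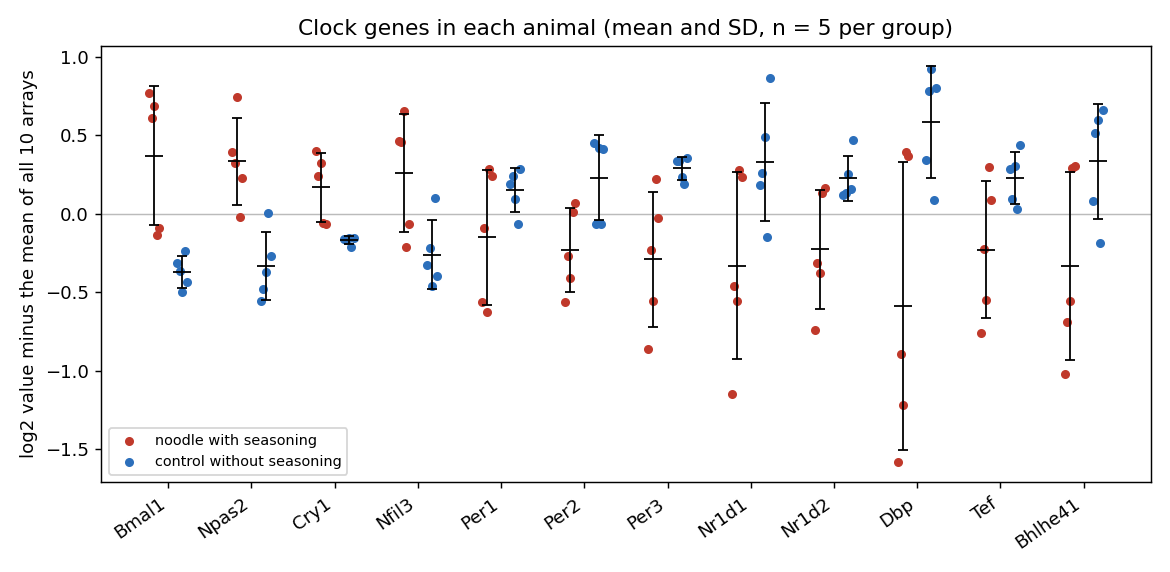
Log2 value of 12 clock genes in each animal, minus the gene's mean over the 10 arrays, with the mean and SD of each group (n = 5). Dbp differed by -1.17 and Bmal1 by 0.74, and the noodle animals are more spread than the controls in every gene shown but Per2.

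Genes of lipid metabolism did not pass the threshold. On the deposited values none of the 11 lipid lists passed in camera, and in these lists 0 genes passed when adjusted over the list alone. The lists depended on the scaling and on single animals. With quantile normalization 6 of the 11 passed as lower and with centring 5, among them beta-oxidation (adjusted p = 0.000619 and 4.66e-05) and lipolysis (adjusted p = 0.00569 and 0.0017). Lower calls were not particular to lipid lists, as 24 lists in all passed as lower with quantile normalization and 22 with centring, and 0 as higher. Both scalings also raised the median difference of all probe sets, from 4.19e-06 to 0.00124 and 0.00166. These calls alone therefore do not show that lipid genes fell. Beta-oxidation passed as higher without noodle animal 4 (adjusted p = 0.01) or control animal 5 (0.0138), and fatty acid synthesis without control animal 5 (0.044). Cholesterol synthesis passed as higher without noodle animal 4 (adjusted p = 0.0358), noodle animal 10 (0.00224) or control animal 2 (0.0326), and thermogenic genes with the 3-prime to 5-prime covariate (0.0364). In fatty acid synthesis, 10 of the 15 variable members were higher and 5 lower. Acly, which makes the acetyl-CoA for synthesis, differed by 0.46 ± 0.31, Slc25a1 by 0.22 ± 0.20, Mlxipl by 0.16 ± 0.14 and Mid1ip1 by 0.14 ± 0.12. Fasn, the fatty acid synthase, differed by -0.07 ± 0.43, the desaturase Scd by -0.32 ± 0.54 and Srebf1 by -0.002 ± 0.135. Single animals carried much of these values, with Acly at 0.222 without noodle animal 1, Slc25a1 at 0.0684 without control animal 14, Mlxipl at 0.069 and Mid1ip1 at 0.0582 without noodle animal 13 and Scd at -0.0168 without control animal 5. In cholesterol synthesis, 8 of 8 variable members were higher, with Lss at 0.29 ± 0.17, Dhcr7 at 0.28 ± 0.18 and Fdps at 0.20 ± 0.14, and an adjusted p of 0.135 for the list (p = 0.408 with an estimated correlation). Without noodle animal 1 Fdps differed by 0.0981, and without control animal 2 Dhcr7 differed by 0.423.

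In lipolysis, 3 of the 9 variable members were higher and 6 lower. Mgll, the monoglyceride lipase, differed by -0.18 ± 0.07, with its 2 other variable probe sets in the same direction. G0s2, an inhibitor of the main triglyceride lipase, differed by 0.36 ± 0.18 (0.223 without control animal 8) and Gnai1 by 0.23 ± 0.11. The lipases Pnpla2 and Lipe differed by -0.09 ± 0.08 and -0.04 ± 0.10. In fatty acid uptake, the transporter Cd36 differed by 0.04 ± 0.01 and Gpihbp1, which holds lipoprotein lipase on capillaries, by -0.12 ± 0.05. In triglyceride synthesis, Lpin1 differed by -0.17 ± 0.08 and Lpin2 by 0.12 ± 0.17 (0.0135 without noodle animal 10 and 0.0136 without control animal 14), and among lipid droplet genes Plin4 differed by -0.12 ± 0.10 and Hilpda by -0.25 ± 0.22. In oxidation, Acaa2 differed by 0.25 ± 0.21, Acads by -0.09 ± 0.09, Cpt1a by -0.08 ± 0.06, Cpt1b by 0.02 ± 0.16 and Phyh by 0.19 ± 0.10. Without control animal 5, Acaa2 differed by 0.401 and Acads by -0.00934, and without control animal 2, Acaa2 differed by 0.101.

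Among thermogenic genes, the mitochondrial carrier Ucp3 had the smallest p. It differed by 0.47 ± 0.12, or 1.39-fold, and 5 of 5 noodle rats lay above every control, with its other variable probe set in the same direction. Its adjusted p was 0.971 over all genes, 0.0608 over the list of thermogenic genes alone and 0.0486 over that of thyroid hormone targets alone. Ucp1 differed by 0.29 ± 0.28 (0.124 without noodle animal 10). The adipokine genes Lep and Metrnl differed by 0.06 ± 0.25 and -0.19 ± 0.12, and the transcription factor genes Pparg and Klf4 by -0.10 ± 0.21 and 0.17 ± 0.12. Adipoq and Lpl, at 12.7 and 13.1 in both groups, have compressed probe sets, so the size of a difference cannot be read from them. Signs for Lep, Fasn, Srebf1, Pparg, Cpt1b and Lipe turned when single animals were left out. Of the 45 variable genes taken by the naming rule, 26 moved by over 1.5 times or turned when 1 animal was left out.

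Of the 55 lists, 6 passed in camera with the preset correlation, and 0 did with an estimated correlation or in fry. Oxidative phosphorylation was higher (adjusted p = 0.00285, and p = 0.411 with an estimated correlation), with 36 of 40 members higher. Its member Cox6c differed by 0.13 ± 0.06. Ribosomal proteins (adjusted p = 0.000329, and p = 0.178 with an estimated correlation) were higher in 19 of 21 members, and the proteasome (adjusted p = 0.00365, and p = 0.0799 with an estimated correlation) in 21 of 25. The ribosomal and proteasome lists had 1 variable member each, and that of the ribosomal list was lower, at -0.03, while the median of the list was 9.49e-05. Of the 22 variable members of oxidative phosphorylation, 18 were higher and 4 lower. Under quantile normalization all 3 lists turned lower relative to the other genes. The adjusted p was 0.00455 for ribosomal proteins, 0.0731 for oxidative phosphorylation and 0.108 for the proteasome. Centring the arrays on their medians ended all 3 calls and turned oxidative phosphorylation lower relative to the other genes (adjusted p = 0.712). Centring adds the same amount to every difference, which raised the median of all probe sets to 0.00166, so no member fell by it. The oxidative phosphorylation call also ended without noodle animal 1 (adjusted p = 0.0875), noodle animal 13 (0.462) or control animal 11 (0.117), and the proteasome call without noodle animal 13 (0.144) or control animal 11 (0.122) and with the hybridization (0.112) or the 3-prime to 5-prime covariate (0.919). Oxidative phosphorylation did not pass with variable probe sets only (0.0712). An intensity trend ended the ribosomal call (0.164). The 3-prime to 5-prime difference given above, a sign of RNA quality, also differed between the groups.

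Among cell type lists, macrophage markers were higher (adjusted p = 0.00459, and p = 0.26 with an estimated correlation) in 18 of 21 members. The complement gene C1qa differed by 0.36 ± 0.18, Aif1 by 0.18 ± 0.10 and Ctss by 0.16 ± 0.09, while Trem2, a receptor of lipid-associated macrophages, differed by -0.30 ± 0.14. With the 3-prime to 5-prime covariate this list turned direction (adjusted p = 0.919), and it did not pass under quantile normalization (adjusted p = 0.262) or centring (adjusted p = 0.941), nor without noodle animal 1 (0.144) or 4 (0.0515) or control animal 5 (0.0802) or 11 (0.122). With variable probe sets only, the macrophage list was the 1 list of 38 that passed (adjusted p = 0.00276, and p = 0.236 with an estimated correlation). Red blood cell markers were lower (adjusted p = 0.00276, and p = 0.0831 with an estimated correlation) in 7 of 8 members. Only 3 of these members were variable, all of them lower, and the median of the list was -0.000993. Alas2, the heme synthesis enzyme of red cells, differed by -0.54 ± 0.21, the haemoglobin gene Hbb by -0.16 ± 0.08 (-0.0873 without noodle animal 4) and Ahsp by -0.21 ± 0.12. Mesothelial markers were lower (adjusted p = 0.0123, and p = 0.256 with an estimated correlation) in 11 of 11 members, with the keratins Krt8, Krt18 and Krt7 at -0.54 ± 0.17, -0.44 ± 0.22 and -0.22 ± 0.24. Without control animal 14, Krt7 differed by -0.0456. The mesothelial call ended without noodle animal 1 (adjusted p = 0.0875) or 7 (0.16) or control animal 11 (0.208) or 14 (0.346), with array weights (0.171), without the dimmest 50% of probe sets (0.102) and with variable probe sets only (0.118). The hybridization covariate ended the mesothelial call (adjusted p = 0.434) and that of red blood cell markers (0.0961). Adipocyte markers did not pass, with 10 of 19 higher and 9 lower (adjusted p = 0.992). They passed as lower relative to the other genes under quantile normalization and centring, among 24 and 22 lists that did so. The number of lists past the threshold was 3 without noodle animal 1, 15 without noodle animal 4, 11 without control animal 5 and 2 without control animal 11.

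**Figure D3:**
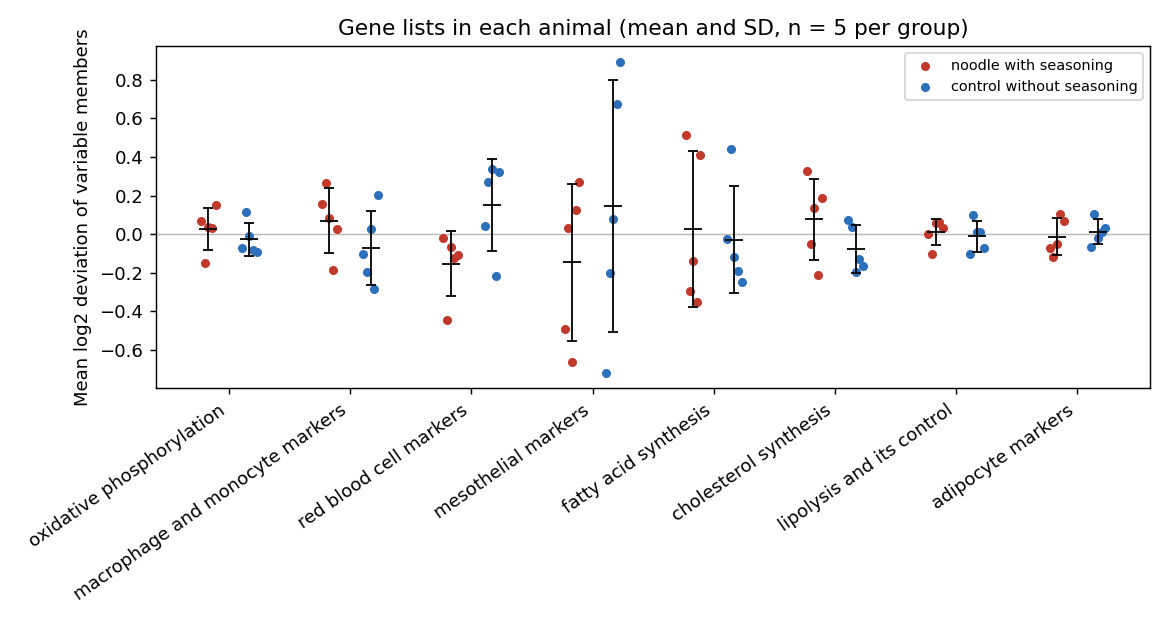
Mean of the variable members of 8 gene lists in each animal, as the log2 deviation from the mean of all arrays, with the mean and SD of each group (n = 5). The groups overlap in every list shown, and mesothelial markers spread widely, with an SD of 0.407 in the noodle group and 0.655 in the controls.

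The genes with the smallest p in each direction were mostly compressed. Higher were Emg1, Ascc3, Rin2, Lnx2, Hsd17b1 and Pank4, with differences from 0.00022 for Lnx2 to 0.00064 for Emg1. Lower were Micall2, Fam8a1, Ubr4 and C8h11orf52, with differences down to -0.00045 for Ubr4, and 2 variable genes. Those 4 compressed genes turned higher under both quantile normalization and centring. The variable genes were Cyb561a3, at -0.34 ± 0.06, and the gap junction gene Gja1, at -0.37 ± 0.07, both below every control in 5 of 5 noodle rats, with an adjusted p of 0.942 each. The 12 variable genes with the smallest p per direction were chosen after the values were seen. Besides the clock genes and Ucp3, those higher were Pfdn6 (0.24 ± 0.05), Mpzl2 (0.42 ± 0.12), Dtx4 (0.43 ± 0.12), Ykt6 (0.36 ± 0.11) and Dynlt3 (0.28 ± 0.08), with Ormdl3, Anp32a and Nedd9 between 0.10 and 0.13. Those lower were Pim3 (-0.59 ± 0.17), Masp1 (-0.44 ± 0.12), Crim1 (-0.38 ± 0.10), Eepd1 (-0.34 ± 0.08) and Ndrg1 (-0.33 ± 0.08), with Tmem98, Tinagl1, Abcc9, Resf1 and Dock4 between -0.31 and -0.02. None of these passed the threshold over all genes.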

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

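Of 248 groups of 5 animals examined, over 79 variable genes, 42 list means and 3 array measures, 20 had 1 animal far from the other 4, where chance gives about 12.4 (about 1 in 20). Noodle animal 4 accounted for 7 of them and control animal 14 for 5. In noodle animal 4, Alas2 stood at 8.16 against 8.68 to 8.77 in the other noodle rats and Hbb at 12.9 against 13.2 to 13.3, and the mean of red blood cell markers stood at -0.45. Of its other list means, mast cell markers stood at 0.28 against -0.24 to -0.15 in the other noodle rats, endothelial markers at 0.22 against -0.13 to -0.06, smooth muscle and pericyte markers at 0.22 against -0.09 to -0.06, and branched-chain amino acid breakdown at -0.20 against 0.03 to 0.12.

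In control animal 14, Lpin2 stood at 7.05, Ucp3 at 6.79 against 7.14 to 7.27 in the other controls, Tmem98 at 7.88 and the mean of xenobiotic metabolism at 0.20. Its mean correlation with the other arrays was 0.9948, against 0.9959 to 0.9962 in the other controls. In control animal 5, Acads stood at 8.50 and the mean of fatty acid uptake at 0.20. In control animal 2, Pparg stood at 9.40 and Dock4 at 6.40, and in control animal 11, Cry1 stood at 6.14. Krt7 stood at 5.26 in noodle animal 7, Resf1 at 8.77 in noodle animal 1, and the mean of endoplasmic reticulum stress at 0.13 in noodle animal 13.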

How the results depend on the processing

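Changed probe sets stayed at 0 in limma under each alternative except without control animal 14, so leaving out single animals gave 0 to 1 in all and 0 to 1 higher. The rank product gave 961, with 400 higher and 561 lower. It permutes values across probe sets whose spreads differ widely, and in simulated data with no change it called 754 to 842. Its construction can thus account for much of the count, and the source of the rest was not tested. The tests on variable probe sets only and with the hybridization controls as a covariate, and the clock count, were chosen after the data were seen. The 6 changed gene lists became 24 with quantile normalization and 22 with median centring, all of them lower, 11 with array weights, 1 with variable probe sets only, 0 with an estimated correlation, 0 in fry and 2 to 15 without single animals. The median difference of all probe sets was 0.00124 with quantile normalization and 0.00166 with centring, above the median absolute difference of the compressed probe sets of 8.48e-05. The 8 clock genes adjusted over the list alone became 3 with quantile normalization, with a trend, with trend and robust, with the mean of a gene's probe sets and with the largest-variance representative, 5 with either filter, the floor or the hybridization covariate, 0 with array weights or the 3-prime to 5-prime covariate, and 0 to 13 without single animals. For the other changes the cause was not tested. Of 91 genes, the variable named ones with the compressed ones named by smallest p or in advance, 78 kept their direction in every setting. Of all 44 compressed genes that the rule took, 17 turned with quantile normalization and 15 with centring. Among gene lists, the direction turned with quantile normalization for ribosomal proteins (adjusted p = 0.00455), oxidative phosphorylation (adjusted p = 0.0731) and the proteasome (adjusted p = 0.108), with centring for oxidative phosphorylation (adjusted p = 0.712), and with the 3-prime to 5-prime covariate for macrophage markers (adjusted p = 0.919). Among genes, none of which passed the threshold in these settings, it turned to log2 differences of 0.000232 for Srebf1, 0.00171 for Micall2, 0.00188 for Fam8a1, 0.00724 for Ubr4 and 0.00494 for C8h11orf52 with quantile normalization. With centring the log2 differences were 0.00146 for Micall2, 0.00133 for Fam8a1, 0.0012 for Ubr4 and 0.00128 for C8h11orf52. With array weights they were -0.0151 for Lep, 0.0814 for Pparg, 0.0318 for Srebf1 and 0.013 for Rora, and with the animal number 0.0266 for Srebf1. With the 3-prime to 5-prime covariate they were 0.000292 for Plin4, 0.0198 for Acads, -0.41 for Lep and 0.17 for Lipe, and with the hybridization covariate -0.0571 for Lep, 0.00968 for Fasn and -0.123 for Cpt1b. Without single animals the log2 differences ranged from -0.063 to 0.198 for Lep, -0.22 to 0.0638 for Pparg, -0.0955 to 0.0538 for Srebf1, -0.301 to 0.14 for Fasn, -0.0952 to 0.021 for Lipe, -0.0569 to 0.102 for Cpt1b and -0.0226 to 0.013 for Rora. No paired analysis was run, because the labels do not say which animals were fed as pairs.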

Other observations

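The tests of the clock genes with covariates and the splits of the arrays, except those for the rank product, were chosen only after the result was seen. For the gene lists the covariate and the estimated correlation were planned, and using them to weigh explanations was chosen after. Some gene groups not yet described leaned one way without passing in camera on the deposited values. Glucocorticoid-responsive genes and mast cell markers passed as lower under both scalings, but so did many other lists, with 24 lower under quantile normalization and 22 under centring. On the deposited values, camera with an estimated correlation gave p = 0.254 and 0.233 for these lists. Of the 11 variable glucocorticoid-responsive genes, 10 were lower in the noodle group, with a mean of -0.09 ± 0.22 against 0.09 ± 0.10 in the controls (SD, n = 5, exact permutation p = 0.127, adjusted p = 0.983 over 42 lists). All 5 variable mast cell markers were lower, though noodle animal 4 had a mean of 0.28 against -0.24 to -0.15 in the other noodle rats. Of 6 variable MHC class II genes, 5 were higher. Bcl6 differed by 1.0 ± 0.35 and Cish, a target of growth hormone signalling, by -1.33 ± 0.52, with an SD of 1.19 in the controls and 0.0544 in the noodle group. Both were chosen after their values were seen, and both had an adjusted p of 0.993.

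The clock genes were weighed first. As a list by itself, 3 of 100 splits of the arrays, the real one included, gave at least 8 genes, with 14 as the highest other, but the list was picked for this count, so that says nothing on chance. As the best of all 55 lists, 14 of 100 splits gave as many, with 33 as the highest other. Chance therefore cannot be excluded once the choice of the list is counted. The split with 33 had 4 noodle animals in 1 group, so it is close to the diet grouping. A split with 3 noodle animals in 1 group gave 16, so groupings that mix the diets also reached high counts. Within the groups, animals with higher Bmal1, Npas2, Cry1 and Nfil3 had lower Per, Dbp, Tef, Nr1d and Bhlhe41 transcripts (r = -0.922, permutation p = 0.00648, rho = -0.927, permutation p = 0.00464, and r = -0.917 without the 2 farthest animals), which is consistent with animals differing in clock phase at dissection, whether by diet or by time of day, which the labels do not give. The difference between the opposed sets was 1.16 ± 0.38 (SE). With the animal number as a covariate it was 1.09 ± 0.34 (95% interval 0.287 to 1.89). The numbers of the groups interleave (means 7 and 8), so a linear trend along them can account for little of the difference. Handling that did not follow the numbers in a straight line was not tested and stays open. With the 3-prime to 5-prime difference as a covariate it was 1.14 ± 0.53 (-0.106 to 2.39). The size hardly moved but the error grew, so RNA quality cannot be told apart from diet. Usp2, Tspan4 and Wee1, outputs of the clock outside the list, were lower on average (-0.0288, exact permutation p = 0.0476), as set down beforehand for a shift of clock outputs, but this rests on Tspan4 (-0.0847), the others being compressed.

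The difference between the opposed sets, by animal, was 1.41, 0.803 and 1.21 in noodle animals 1, 4 and 7, and -0.344 and -0.179 in noodle animals 10 and 13. The controls lay between -0.848 and -0.0873.

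The flatness of most probe sets was weighed next. In 600 genes with both kinds of probe set, a compressed and a variable probe set of the same gene had a median correlation of 0.537 over the arrays, against -0.0696 to 0.072 in 1000 random pairings. A pair of variable probe sets of the same gene had a median of 0.865 in 234 genes. A candidate explanation for these genes is a summarisation that shrank a real signal in their compressed probe sets and kept its direction. Compressed probe sets of genes without a variable one were not covered by this test. The method is not given, and no biological explanation was tested.

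The shifted gene lists were weighed last. Of 100 splits, 67 gave at least the 6 lists seen between the diets, so chance cannot be excluded. A split with 3 noodle animals in 1 group gave 21, so the arrays hold structure apart from diet. With an estimated correlation 0 lists passed, as needed if genes of a list vary together between animals, which may account for the calls. With the 3-prime to 5-prime difference as a covariate 4 of the 6 lists passed, with adjusted p from 0.00712 for mesothelial markers to 0.0456 for oxidative phosphorylation. The proteasome and macrophage lists did not pass with it (adjusted p = 0.919 each). As no call held with an estimated correlation, a kept call decides nothing, and RNA quality and diet cannot be told apart for these lists.

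For the 0 changed probe sets the splits say nothing, since all 100 reach 0, with 2 as the highest other. For the 212 variable probe sets at an unadjusted p under 0.05, 16 splits gave as many, with 458 as the highest other. For the 961 probe sets of the rank product, 30 splits gave as many, with 1435 as the highest other, so chance cannot be excluded for either count.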
